A study of Homo sapiens with 16 samples.

How the data were processed

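Cells of the line Molm14 were grown in RPMI with fetal bovine serum and treated for 7 days, with fresh medium and compound on day 4. The extraction protocol speaks of RNA taken 3 days after a sort, which conflicts with the treatment description, and the treatment description was followed. Paired-end libraries of 2 x 150 bases were sequenced, and the submitters named kallisto, DESeq2 and the hg38 build. Versions of these tools and the transcript annotation behind the table are not given in the sources used here.

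The processed table held 22445 Ensembl gene IDs for 16 libraries, 4 per group, and no columns of other samples. Of these IDs 20784 matched GENCODE v29, from which symbols, types and GRCh38 positions were taken, and 1661 did not match and were kept by ID. Matched IDs covered 16818 protein-coding genes and 3895 pseudogenes. The deposited values were log2 values that the authors had scaled between samples and variance-stabilised, in the form DESeq2 gives, with the same lowest value of 6.28106 in each library standing for a count of 0. They were turned back into normalised counts with the inverse of that transformation. Low values then lay on evenly spaced steps, with 66.6% to 70.2% of them within 0.1 read of a whole number, and read totals estimated from the steps were 20.7 to 27.3 M per library. These are estimates, and levels are given as normalised counts. The most abundant gene, EEF1A1, held 3.2% to 4.2% of a library. Pearson correlations over the 120 pairs of libraries were 0.982 to 0.996, and at most 850 values were identical in any pair, so no library was a copy of another. Raw reads were not analysed here.

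The design chosen before the table was seen used edgeR on counts, and its branch for values that are not counts was followed. Genes with a normalised count above 1 in at least 4 libraries were tested (22331). Limma-trend was fitted to log2 of the normalised count plus 1, with 4 group means over 16 libraries and no block (12 residual degrees of freedom, median prior 6.8), with empirical Bayes moderation (trend and robust) and Benjamini-Hochberg adjustment within each comparison, and genes with an adjusted p under 0.05 were called. Comparisons were each treatment against DMSO, Combo against each single treatment, iDOT1L against iEZH2, and the interaction, that is Combo minus iDOT1L minus iEZH2 plus DMSO. Fold changes are differences of fitted group means in log2 with their SE from limma, and group levels are means and SD of normalised counts. Where a group had no reads, the fold is a lower bound from a count of 3 spread over the group.

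Residual correlations between replicates of the same number were all above 0.1 for iDOT1L and DMSO (0.138 to 0.458), iEZH2 and DMSO (0.125 to 0.501) and iDOT1L and iEZH2 (0.158 to 0.577). These comparisons were also read from a fit of all 16 libraries, Combo included, with the replicate number as a block. The labels do not say what the number stands for.

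Lists of genes, 30 in number, were written from textbook knowledge before the table was seen. They were tested with limma camera with a preset inter-gene correlation of 0.01 and BH adjustment over the lists of a comparison. The same test with a correlation estimated per list is given beside each call of the fit without a block, and of the calls with the preset correlation it kept 1 in Combo against iDOT1L and 1 in iDOT1L against iEZH2, both for developmental regulators. Members called over all genes and over the list alone were counted. The genes named were chosen by a rule set before the data were examined. It took 23 fixed genes of the KMT2A, DOT1L, PRC2, myeloid and cell cycle fields. It also took the 10 largest rises and 10 largest falls against DMSO (5 in comparisons between treatments) among called genes with a mean log2 value of at least 2 in the higher group and no overlap between the groups. Last, it took up to 4 members with the lowest adjusted p of each called list. Pseudogenes and clone names without an approved symbol were passed over, and a few genes that the rule took are not reported here. For each named gene the share of 31-base words of its transcripts that occur in other genes was counted, and above 20% the level was taken as uncertain.

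Expected overlap of calls was taken from simulated libraries, from the product of list sizes, and from fits with the DMSO libraries divided between the comparisons. The simulation drew all 16 libraries, DMSO included, around the DMSO means without any change, in 100 sets. Calls were recounted under all 35 divisions of 8 libraries into 4 and 4. The fitting step was run on made-up normalised counts with planted changes, drawn independently for each gene and library without replicate effects or back-transformation. It found 46.9% of 2-fold and 63.3% of 4-fold changes for iDOT1L against DMSO, or 87.5% and 100% at a mean of at least 50, and 48.5% and 58.6% for Combo against DMSO, or 92% and 98%. It called 4 of 21646 unchanged genes in the first and 4 of 21644 in the second, and 0 of 21840 in iEZH2 against DMSO, where none was planted. The made-up libraries lack the correlations of the real ones, where false calls may be more frequent. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

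The alternatives tried were a replicate block, quantile normalization and library size alone as scaling, limma without a trend, other filters (none, or at least 1 CPM in at least 4 libraries), the groups compared alone, a change of at least 2-fold, an adjusted p under 0.01 for overlaps, pseudocounts of 0.1 and 5, and each library left out in turn. Added after the data were examined were the deposited values without back-transformation, library quality weights, matched IDs alone, the groups compared with the replicate block, an exact permutation of list scores, list members without each library, and a correction for transcript length and GC content.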

Results

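Molm14 cells, an acute myeloid leukaemia line with a KMT2A rearrangement, were grown for 7 days with DMSO, with 0.16 uM EPZ5676 against DOT1L (iDOT1L), with 0.3 uM GSK126 against EZH2 (iEZH2) or with both compounds (Combo). Medium and compound were renewed on day 4, and 4 libraries were sequenced per group. DOT1L methylates histone H3 at lysine 79 and EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), methylates lysine 27. Genes of the KMT2A-fusion programme such as MEF2C and PBX3 fell with iDOT1L and with Combo. Of 23 cholesterol synthesis genes 4 fell with iDOT1L, 19 with iEZH2 and 22 with Combo, DHCR7 each time. With replicates of the same number treated as pairs, 17 of them fell with iDOT1L and 21 with iEZH2. Of 22331 genes tested with limma and Benjamini-Hochberg (BH) adjustment, 1396 changed with iDOT1L, 748 with iEZH2 and 3579 with Combo against DMSO. The p-values measure only the spread between these samples, because the labels do not say whether the 4 replicates of a group were separate cultures.

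In the principal component plot, the first component held 32.4% of the variance over 12270 genes and the second 19.9%. DMSO and Combo libraries lay at opposite ends of the first component and both single treatments lay between them. The normalised levels of the targets themselves were close to those of DMSO. DOT1L (ENSG00000104885) averaged 6796 ± 101 normalised counts in DMSO and 6500 ± 861 with iDOT1L (log2 fold change -0.07), and EZH2 (ENSG00000106462) averaged 1906 ± 221 in DMSO and 2267 ± 284 with iEZH2 (0.25). Neither gene passed in any comparison without pairing, and neither did MYC, MYB, BCL2, CD14, CD34, CDKN1C, CDKN2A or CDKN2B. MYC differed from DMSO by -0.05 with iDOT1L, 0.10 with iEZH2 and 0.16 with Combo, and BCL2 by 0.30, -0.07 and 0.06. With replicates of the same number treated as pairs, EZH2 was called higher with iEZH2 than with DMSO (adjusted p = 0.0166) or iDOT1L (adjusted p = 0.000502), and BCL2 was called higher with iDOT1L than with DMSO (adjusted p = 0.0241) or iEZH2 (adjusted p = 0.00588). PRC2 subunits, stem and progenitor markers, lymphoid markers and CDK inhibitors were called as lists in no comparison without pairing. With Combo against DMSO 2 of 13 PRC2 genes rose and 4 fell, 2 of 25 stem and progenitor genes rose and 3 fell, and 4 of 24 lymphoid genes rose and 3 fell. In an exact permutation of list scores no list passed after BH adjustment (lowest adjusted p = 0.0779). The smallest permutation p before adjustment is 0.0286 with 4 against 4 libraries, which 11 of 30 lists reached in Combo against DMSO.

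**Figure D1:**
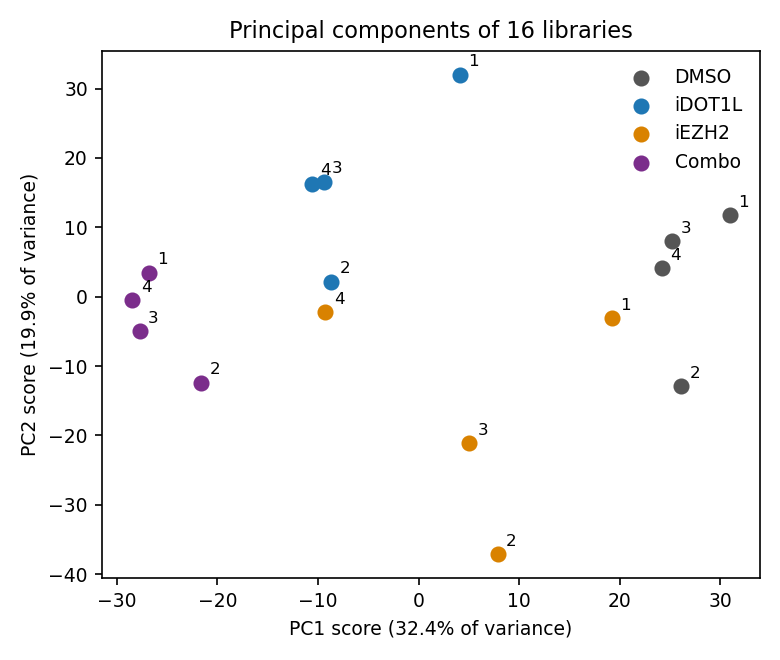
Principal components of the 16 libraries on log2 normalised counts, with the first component (32.4% of variance) on the horizontal and the second (19.9%) on the vertical axis, coloured by treatment, with the replicate number beside each point. DMSO and Combo libraries lie at opposite ends of the first component with both single treatments between them.

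**Figure D2:**
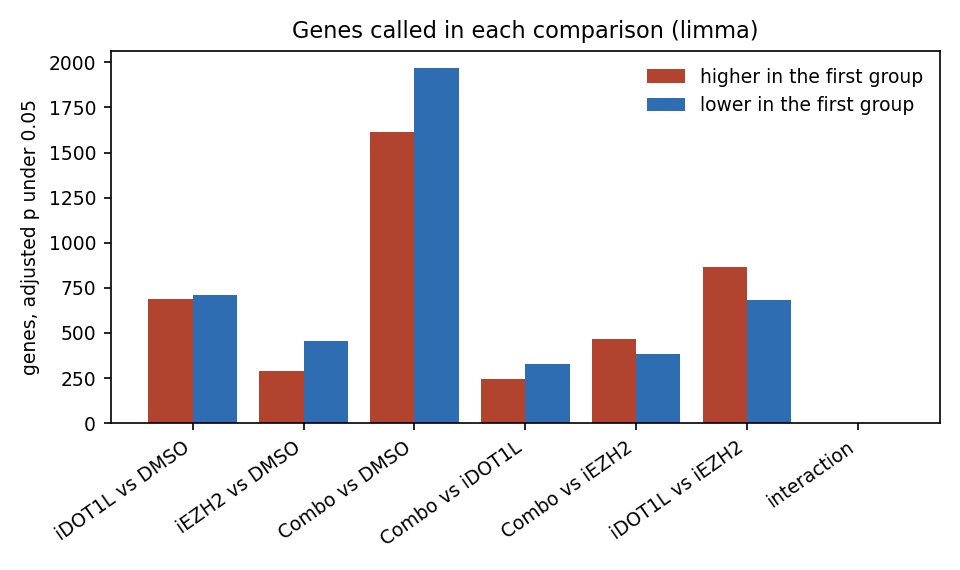
Number of genes higher and lower in each comparison by limma with a BH-adjusted p under 0.05. Combo against DMSO has 1613 higher and 1966 lower, and the interaction has 0.

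With iDOT1L, 16 of 30 genes of the KMT2A-fusion and HOXA list fell, and 14 of 49 monocyte and macrophage markers rose while 5 fell. MEF2C (ENSG00000081189, chr5:88717117-88904257, GRCh38), which encodes a transcription factor of myeloid and lymphoid progenitors, fell from 6432 ± 306 to 2830 ± 736 normalised counts (mean ± SD, n = 4; log2 fold change -1.21 ± 0.17 SE, limma adjusted p = 0.000238). PBX3 (ENSG00000167081, chr9:125747345-125967377), a cofactor of HOX proteins, fell from 2327 ± 118 to 999.1 ± 195 (-1.24 ± 0.14, adjusted p = 2.06e-05). MEIS1 (ENSG00000143995, chr2:66433452-66573869), another HOX cofactor, fell from 1582 ± 128 to 873.6 ± 122 (-0.86 ± 0.13, adjusted p = 0.000379), and HMGA2, a chromatin architectural gene, fell by 1.61 ± 0.16 (adjusted p = 7.43e-06). FLT3 (ENSG00000122025, chr13:28003274-28100592), the receptor tyrosine kinase gene, fell from 9243 ± 1170 to 6139 ± 1340 (-0.61 ± 0.14, adjusted p = 0.0105). Of the 30 genes in the KMT2A-fusion and HOXA list, 16 fell, none rose and 14 did not pass, and adjusted over the list alone 19 fell and 1 rose (median -0.44; camera adjusted p = 2.73e-13, or 0.173 with an estimated correlation). HOXA9 was among those that did not pass (-0.30) and HOXA10 fell by 0.43 ± 0.11 (adjusted p = 0.0211). HOXA10 was no longer called in 5 of 8 fits that each left out 1 library (DMSO 1, 3 and 4, iDOT1L 2 and 3; highest adjusted p = 0.0747). Of the 31-base words, 24.3% for HOXA9 and 24.5% for HOXA10 also occur in other genes, so both levels are uncertain.

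MPO (ENSG00000005381, chr17:58269856-58280935), the peroxidase of neutrophil granules, rose from 862.4 ± 144 to 5031 ± 519 normalised counts (log2 fold change 2.55 ± 0.23, limma adjusted p = 7.43e-06), and LYZ (ENSG00000090382, chr12:69348341-69354234), the lysozyme gene, rose from 2463 ± 177 to 9051 ± 2150 (1.85 ± 0.22, adjusted p = 6.79e-05). The LYZ level is uncertain because 39.3% of its 31-base words occur elsewhere. The chemokine receptor gene CCR2 (ENSG00000121807, chr3:46353734-46360928) rose by 3.05 ± 0.25, the interferon-inducible nuclear protein gene MNDA by 2.56 ± 0.21 and the endotoxin receptor gene TLR4 by 2.43 ± 0.25. Of 49 monocyte and macrophage markers, 14 rose, 5 fell and 30 did not pass (median 0.34; camera adjusted p = 2.47e-05, or 0.276 with an estimated correlation). Among the genes that fell was the integrin gene ITGAM (-1.29 ± 0.34, adjusted p = 0.0311), which was no longer called in 6 of 8 fits without 1 library (DMSO 1, 3 and 4, iDOT1L 2, 3 and 4; highest adjusted p = 0.0954). Only 1 of these markers fell without DMSO 1, 3 or 4 or iDOT1L 2 or 3, and 2 fell without iDOT1L 4. In MHC class II, 3 of 10 genes rose and none fell (median 0.58; camera adjusted p = 0.00135, or 0.173 with an estimated correlation). CD74, the invariant chain, rose by 0.54 ± 0.13 (adjusted p = 0.013), and HLA-DQB1 rose by 1.44 ± 0.29 (adjusted p = 0.00402).

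The largest rises with iDOT1L included genes that were almost silent in DMSO. NME8 (chr7:37848597-37900401), which encodes a thioredoxin-domain protein of cilia, was not detected in DMSO and averaged 21.95 ± 4.77, at least 27.1-fold higher. The serpin gene SERPINB2 (ENSG00000197632, chr18:63871692-63903890), an inhibitor of plasminogen activators, rose from 0.8104 ± 1.62 to 22.27 ± 2.72 (log2 fold change 4.01 ± 0.71, limma adjusted p = 0.00179). Its neighbour SERPINB10 (chr18:63897174-63936111), whose span overlaps that of SERPINB2, rose from 2.588 ± 1.37 to 39.0 ± 5.22 (3.55 ± 0.36, adjusted p = 7.43e-06). Of its 31-base words 20.7% also occur in other genes, mainly SERPINB2 (19.2%), so its level is uncertain. SERPINB2 in turn shares 18.9% of its words with SERPINB10, so these rises may not be separate. The lectin receptor gene CLEC12A (chr12:9951316-9995694) rose from 11.88 ± 6.42 to 121.0 ± 22.5 (3.40 ± 0.43, adjusted p = 6.36e-05). The largest falls included the early growth response gene EGR1 (ENSG00000120738, chr5:138465490-138469315), from 184.1 ± 81.3 to 20.75 ± 13.5 (-3.16 ± 0.41, adjusted p = 8.14e-05), and the myosin-binding protein gene MYBPH (chr1:203167811-203175813), from 990.9 ± 156 to 184.0 ± 12.2 (-2.41 ± 0.17, adjusted p = 1.99e-07). SMN2 rose by 3.20 ± 0.65, but 93.4% of its 31-base words are shared with other genes, mainly SMN1, so its reads cannot be assigned.

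Some genes of stress and metabolic lists also fell with iDOT1L, and none of these list calls held with an estimated correlation. Of 23 immediate early and AP-1 genes 7 fell and 1 rose (median -0.54; camera adjusted p = 7.15e-06, or 0.23 with an estimated correlation). NR4A1, an orphan nuclear receptor gene, fell by 1.65 ± 0.21 (limma adjusted p = 5.29e-05) and JUNB fell by 0.66 ± 0.10 (adjusted p = 0.000385). In cholesterol synthesis 4 of 23 genes fell and none rose, and 12 fell when adjusted over the list alone (median -0.34; adjusted p = 2.45e-09, or 0.276). DHCR7, the last reductase of the pathway, fell from 2745 ± 169 to 1656 ± 195 (-0.73 ± 0.11, adjusted p = 0.000232), and without iDOT1L 1 the number of falling members was 7. In glycolysis 6 of 23 genes fell (adjusted p = 9.86e-07, or 0.276), among them ENO1 (-0.39 ± 0.06, adjusted p = 0.000471). Only 3 of them fell without DMSO 1, DMSO 3 or iDOT1L 3, and 4 without DMSO 2, DMSO 4, iDOT1L 2 or iDOT1L 4. Of 30 genes of ATF4 and the unfolded protein response 5 fell and 1 rose (adjusted p = 2.47e-05, or 0.276), including XBP1, a regulator of secretory capacity (-1.20 ± 0.14, adjusted p = 2.03e-05). Between 3 and 6 of them fell when single libraries were left out, with 3 without DMSO 4, iDOT1L 2 or iDOT1L 3. Of 44 interferon-stimulated genes 9 fell and 2 rose (adjusted p = 0.00135, or 0.173), among them OAS3 (-1.65 ± 0.30, adjusted p = 0.00179) and IFIT2 (-2.18 ± 0.44, adjusted p = 0.00426). In that list 5 genes fell without DMSO 3, DMSO 4 or iDOT1L 3 and 6 without iDOT1L 1 or 2, and 0 or 1 rose whichever library was left out.

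Small shifts of whole lists were called in a few more groups with iDOT1L, with few or no single genes past the test. Cytosolic ribosomal protein genes were shifted up (median 0.11; camera adjusted p = 5.36e-05, or 0.66 with an estimated correlation) with 0 of 80 genes called, and mitochondrially encoded mRNAs were shifted up (0.24; adjusted p = 0.0111, or 0.66) with 0 of 13 called. Mitochondrial ribosomal proteins were shifted down with 3 of 76 fallen (adjusted p = 0.00056, or 0.66), including MRPS6 (-0.65 ± 0.10). MYC-responsive genes were shifted down (adjusted p = 0.000111, or 0.66) with LDHA fallen among 58 (-0.54 ± 0.10), and aminoacyl-tRNA synthetases were shifted down (adjusted p = 0.00167, or 0.561) with 0 of 20 called. In the BCL2 family 3 of 16 genes fell (adjusted p = 0.0325, or 0.173). MCL1 fell by 0.38 ± 0.08 and BCL2A1 by 1.61 ± 0.27. BCL2L11 was the third (-0.38 ± 0.11) and was lost in 7 of 8 fits without 1 library, all but the fit without iDOT1L 2 (highest adjusted p = 0.145). The remaining 16 of 30 lists were not called, and of 51 developmental regulators often marked by PRC2 2 rose and 10 fell (adjusted p = 0.124). Among single genes CDKN1A, a cyclin-dependent kinase inhibitor, fell by 0.55 ± 0.09 (adjusted p = 0.000564), CDK6 fell by 0.73 ± 0.21 (adjusted p = 0.0496) and EZH1 rose by 0.45 ± 0.13 (adjusted p = 0.0412). CDK6 was lost in all fits but that without iDOT1L 2 (highest adjusted p = 0.142), and EZH1 in all but that without DMSO 4 (highest adjusted p = 0.125). KIT did not pass (1.26).

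With replicates of the same number treated as pairs, iDOT1L against DMSO gave 2729 genes, the BCL2 family was no longer called (camera adjusted p = 0.0519) and ribosome biogenesis was called lower (adjusted p = 0.0134, or adjusted p = 0.605 with an estimated correlation). Among list members, 17 of cholesterol synthesis, 15 of glycolysis, 13 of the MYC list, 11 of ATF4 and the unfolded protein response, 11 of immediate early genes, 6 each of aminoacyl-tRNA synthetases and mitochondrial ribosomal proteins and 5 each of the BCL2 family and ribosome biogenesis then fell. Rises were called in 7 cytosolic ribosomal protein genes (37 after a correction for transcript length and GC content), 4 interferon-stimulated genes, 3 immediate early genes and 3 of ribosome biogenesis. The mitochondrially encoded mRNAs, glycolysis and the KMT2A-fusion list had 1 rise each, or 12 for the mitochondrially encoded mRNAs after that correction. HOXA9 (adjusted p = 0.00623) was called lower and KIT (adjusted p = 0.0147) higher. Leaving out each library in turn gave 915 to 1279 genes, with 915 without iDOT1L 3.

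With iEZH2 alone, most cholesterol synthesis mRNAs fell. INSIG1 (ENSG00000186480, chr7:155297776-155310235), the sterol sensor that holds SREBP in the endoplasmic reticulum, fell from 7242 ± 1030 to 3164 ± 944 normalised counts (n = 4; log2 fold change -1.23 ± 0.21, limma adjusted p = 0.00436). DHCR7 (ENSG00000172893, chr11:71428193-71452868) fell from 2745 ± 169 to 1487 ± 250 (-0.90 ± 0.11, adjusted p = 0.000173), LSS, lanosterol synthase, by 0.81 ± 0.15 (adjusted p = 0.00469) and IDI1, an isoprenoid isomerase gene, by 0.76 ± 0.13 (adjusted p = 0.00188). Of the 23 genes 19 fell, none rose and 4 did not pass, and adjusted over the list alone 22 fell and 1 rose (median -0.65; camera adjusted p = 1.65e-24, or 0.114 with an estimated correlation). Without DMSO 3 or iEZH2 2 the number was 12. In glycolysis 6 of 23 genes fell (adjusted p = 5.43e-10, or 0.178). SLC16A3, a lactate exporter gene, fell by 0.61 ± 0.10 (adjusted p = 0.00243) and LDHA by 0.45 ± 0.10 (adjusted p = 0.0131). In that list 11 fell without iEZH2 1 and 4 without DMSO 3 or iEZH2 4. Of 23 immediate early genes 6 fell (adjusted p = 5.07e-09, or 0.114). JUND fell by 0.79 ± 0.12 (adjusted p = 0.000856) and NR4A1 by 1.28 ± 0.21 (adjusted p = 0.00169), and 4 fell without DMSO 1, DMSO 3 or iEZH2 4.

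Some genes that PRC2 often silences rose with iEZH2. PAX6 (ENSG00000007372, chr11:31784779-31818062), a regulator of eye and brain development, rose from 96.73 ± 24.5 to 225.2 ± 13.7 (log2 fold change 1.24 ± 0.16, limma adjusted p = 0.00038), and POU4F1 (ENSG00000152192, chr13:78598362-78603560), a sensory neuron factor, rose from 267.7 ± 31 to 466.7 ± 41.8 (0.80 ± 0.10, adjusted p = 0.000342). Shared words were 24.8% for PAX6 and 27.2% for POU4F1, so both levels are uncertain. Of the 51 developmental regulators 4 rose and 1 fell, and adjusted over the list alone 10 rose and 4 fell (median 0.17; camera adjusted p = 0.04, or 0.114 with an estimated correlation). HOXB9 rose by 1.21 ± 0.28 (adjusted p = 0.018) but was lost without DMSO 1 (adjusted p = 0.0564) or DMSO 4. The number of risers was 2 without DMSO 1 or DMSO 4. Among the largest rises were the zinc-finger gene ZNF704 (chr8:80628451-80874781; 2.52 ± 0.44, adjusted p = 0.00436), the B-cell factor gene EBF1 (chr5:158695916-159099761; from 2.278 ± 1.78 to 21.13 ± 15.1, 2.69 ± 0.55, adjusted p = 0.0085) and the small leucine-rich proteoglycan gene LUM (from 1.237 ± 1.53 to 9.376 ± 5.92, 2.34 ± 0.47, adjusted p = 0.00713). The rise of LUM was not particular to iEZH2, since LUM also rose with iDOT1L against DMSO (2.03, limma adjusted p = 0.011). RTL9, a retrotransposon-derived gene, rose by 3.30 ± 0.54 (adjusted p = 0.00185), while the apparent rise of ZNF511-PRAP1 cannot be assigned because 97.3% of its words are shared.

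A minority of myeloid markers fell with iEZH2. Of 49 monocyte and macrophage markers 10 fell, 2 rose and 37 did not pass (median -0.15; camera adjusted p = 0.00633, or 0.638 with an estimated correlation). Among those that fell were MS4A7, a membrane protein gene of macrophages (log2 fold change -0.81 ± 0.14, limma adjusted p = 0.00267), and IRF8, a monocyte-lineage factor (-0.40 ± 0.08, adjusted p = 0.0114). The list score of iEZH2 4 (0.2333) lay above those of all 4 DMSO libraries. The number that fell was 6 without DMSO 1 or iEZH2 2, 3 without DMSO 3 and 4 without DMSO 4, and 4 rose without iEZH2 1. The hexokinase gene HK3 (chr5:176880869-176899332), which is rich in myeloid cells, fell from 63.26 ± 14.7 to 18.42 ± 10.5 (-1.87 ± 0.36, adjusted p = 0.00627), and among the largest falls was CATSPER1 (-2.70 ± 0.47, adjusted p = 0.00274), a sperm calcium channel gene. FLT3 fell from 9243 ± 1170 to 5278 ± 859 (-0.82 ± 0.14, adjusted p = 0.00232) and was the only one of the 23 fixed genes called without pairing. MEF2C (-0.53), PBX3 (-0.07), MEIS1 (-0.12), LYZ (0.74), MPO (0.42), KIT (0.83), ITGAM (-1.16), CDK6 (-0.24), CDKN1A (-0.21), EZH1 (0.34) and both HOXA9 (0.07) and HOXA10 (-0.07) did not pass, and in the KMT2A-fusion and HOXA list 2 of 30 rose and 2 fell (camera adjusted p = 0.105). Among 15 erythroid and megakaryocyte markers EPOR fell (-0.51 ± 0.10, adjusted p = 0.00598) and the list was shifted down (adjusted p = 0.0116, or 0.114).

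Growth-related lists were shifted up with iEZH2 while hardly any member passed alone. For S phase 2 of 44 genes rose (median 0.20; camera adjusted p = 2.25e-08, or 0.585 with an estimated correlation). They were DSCC1 (log2 fold change 0.52 ± 0.12) and HELLS (0.37 ± 0.10), both lost in 6 of 8 fits, without DMSO 1, 3 or 4 or iEZH2 2, 3 or 4 (highest adjusted p = 0.0812 and 0.132). For G2 and M phase 0 of 54 passed (median 0.16; adjusted p = 2.25e-08, or 0.505). The lists of mitochondrially encoded mRNAs (median 0.33; adjusted p = 4.02e-05, or 0.585), cytosolic ribosomal proteins (0.09; adjusted p = 0.000192, or 0.729), oxidative phosphorylation (0.08; adjusted p = 0.000845, or 0.705) and mitochondrial ribosomal proteins (0.08; adjusted p = 0.000929, or 0.705) were shifted up with 0 genes called. Ribosome biogenesis was shifted up (0.13; adjusted p = 8.33e-05, or 0.705) with RRS1 as its one riser of 55 (0.53 ± 0.14), which was lost in 6 of 8 fits, without DMSO 1, 3 or 4 or iEZH2 2, 3 or 4 (highest adjusted p = 0.154). MYC-responsive genes were shifted up (0.10; adjusted p = 0.000679, or 0.705) although the 2 of 58 members that passed fell. Without iEZH2 1, 7 of the mitochondrially encoded mRNAs and 3 genes each of S phase, ribosome biogenesis and the MYC list rose. The remaining 16 of 30 lists were not called, and in MHC class II (test direction down, median 0.15) and the aminoacyl-tRNA synthetases (down, 0.01) the median and the test had opposite signs.

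With replicates as pairs iEZH2 against DMSO gave 2180 genes, and the KMT2A-fusion and HOXA list was called lower (camera adjusted p = 0.0285, or adjusted p = 0.45 with an estimated correlation). Its camera adjusted p was 0.0526 after a correction for length, 0.0213 after one for GC content and 0.0294 after one for both. The developmental regulators were no longer called (adjusted p = 0.0716, and 0.0568 with library size alone as scaling). Among list members, 17 monocyte and macrophage markers, 17 of glycolysis, 6 of the KMT2A-fusion list, 3 of the developmental regulators and 2 erythroid and megakaryocyte markers then fell. Rises were called in 15 genes of G2 and M phase, 13 of S phase, 12 of the MYC list and 10 of ribosome biogenesis. They were also called in 9 mitochondrially encoded mRNAs (13 after a correction for length and GC content), 7 developmental regulators and 4 monocyte and macrophage markers. Lists with fewer rises were oxidative phosphorylation and the KMT2A-fusion list (3 each) and the cytosolic (1, or 11 after that correction) and mitochondrial ribosomal proteins (1). ITGAM (adjusted p = 8.11e-05), MEF2C (adjusted p = 0.0153) and CDKN1A (adjusted p = 0.0375) were called lower and EZH1 (adjusted p = 0.0447) higher. Leaving out each library in turn gave 409 to 1046 genes, with 442 without DMSO 1, 409 without DMSO 3, 439 without DMSO 4 and 473 without iEZH2 3.

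**Figure D3:**
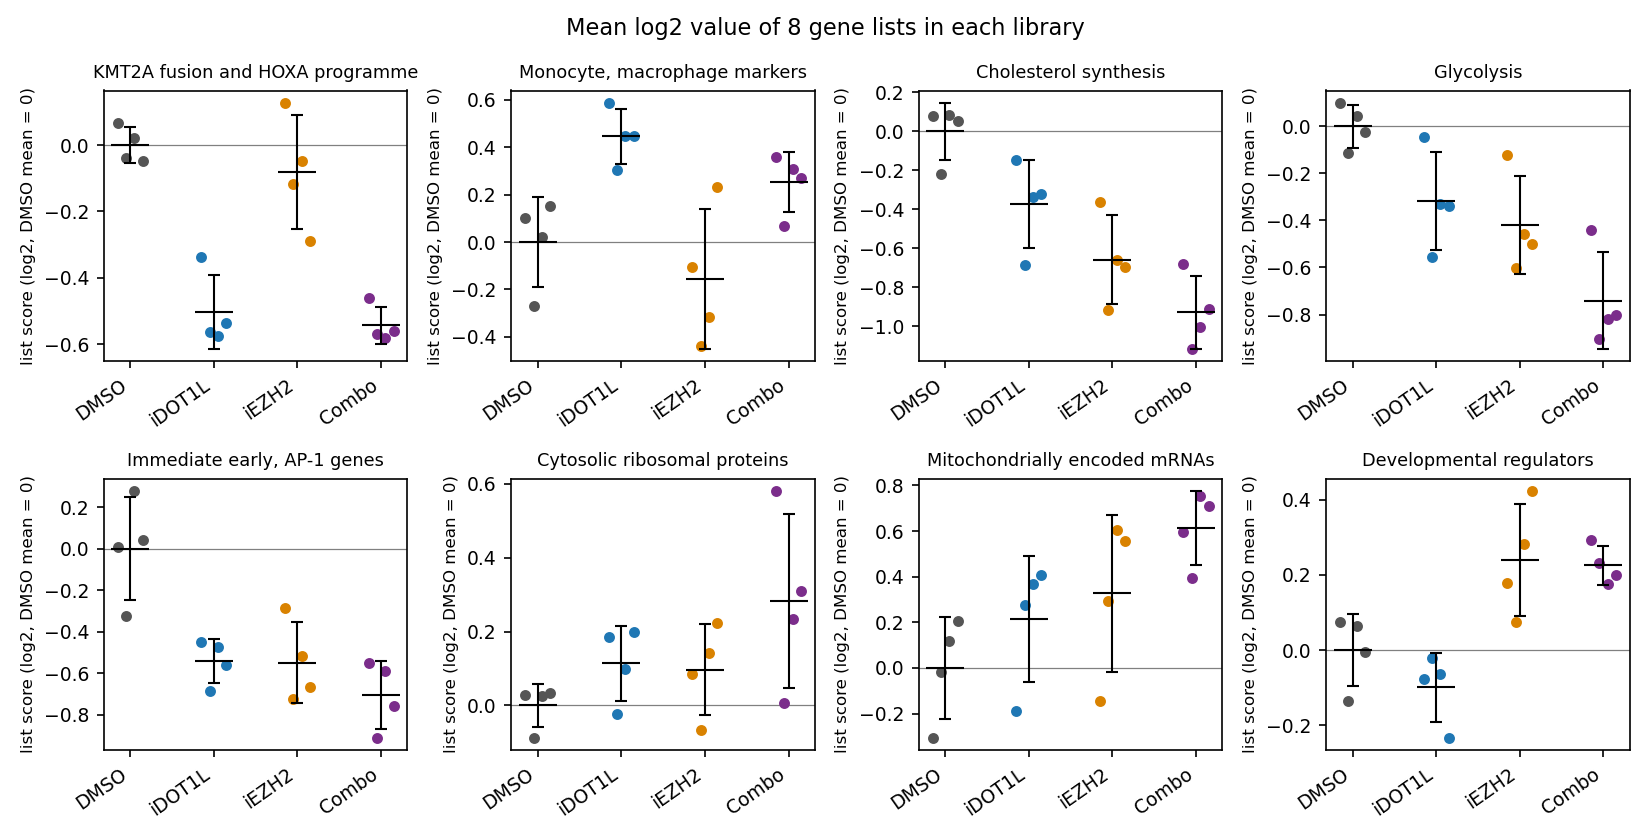
Mean log2 level of 8 gene lists in each library (points, one per library) relative to the DMSO mean, with bars for group means and SD (n = 4). The cholesterol synthesis score averages -0.37 with iDOT1L, -0.66 with iEZH2 and -0.93 with Combo.

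With Combo, cholesterol synthesis was the list with the largest share of fallen genes. DHCR7 fell from 2745 ± 169 to 943.7 ± 58 normalised counts (n = 4; log2 fold change -1.54 ± 0.11, limma adjusted p = 5.06e-08), LSS from 3975 ± 463 to 1629 ± 135 (-1.28 ± 0.15, adjusted p = 7.99e-06) and IDI1 by 1.05 ± 0.13 (adjusted p = 1.05e-05). Of the 23 genes 22 fell and none rose (median -0.85; camera adjusted p = 4.31e-21, or 0.172 with an estimated correlation). In glycolysis 16 of 23 genes fell and none rose (median -0.53; adjusted p = 1.2e-12, or 0.172). LDHA (ENSG00000134333, chr11:18394388-18408425), lactate dehydrogenase A, fell from 33990 ± 495 to 17640 ± 2600 (-0.96 ± 0.10, adjusted p = 2.11e-06) and SLC16A3 fell by 1.04 ± 0.10 (adjusted p = 1.49e-06). Of 23 immediate early genes 10 fell and 1 rose (median -0.84; adjusted p = 2.45e-06, or 0.307). EGR1 fell from 184.1 ± 81.3 to 15.63 ± 4.73 (-3.42 ± 0.41, adjusted p = 1.1e-05) and NR4A1 by 1.87 ± 0.21 (adjusted p = 4.88e-06). Of 30 genes of ATF4 and the unfolded protein response 10 fell and 1 rose (adjusted p = 0.00122, or 0.404). XBP1 (ENSG00000100219, chr22:28794555-28800597) fell from 8899 ± 258 to 2951 ± 247 (-1.60 ± 0.14, adjusted p = 4.14e-07) and EDEM1, a degradation factor of the endoplasmic reticulum, fell by 1.13 ± 0.13 (adjusted p = 7.64e-06).

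Most genes of the KMT2A-fusion list fell with Combo. MEF2C fell to 1745 ± 171 (log2 fold change -1.89 ± 0.17, limma adjusted p = 1.08e-06), FLT3 to 3464 ± 352 (-1.41 ± 0.14, adjusted p = 1.23e-06), MEIS1 to 722.0 ± 58.3 (-1.13 ± 0.13, adjusted p = 8.1e-06) and PBX3 to 1171 ± 198 (2.01-fold lower, adjusted p = 6.07e-05). Of the 30 genes 18 fell, 1 rose and 11 did not pass (median -0.62; camera adjusted p = 8.31e-11, or 0.172 with an estimated correlation). IGF2BP2, an mRNA-binding protein gene, fell by 0.91 ± 0.11 (adjusted p = 7.3e-06) and CDK6 by 0.90 ± 0.21 (adjusted p = 0.00683). HOXA9 (-0.18) did not pass, and HOXA10 (-0.39 ± 0.11, adjusted p = 0.0191) was lost without DMSO 3, Combo 2 or Combo 3 (highest adjusted p = 0.0626). Of 26 genes of the DOT1L, super elongation and KMT2A complexes 6 fell and 2 rose (adjusted p = 0.0193, or 0.404). MLLT10, a DOT1L partner, fell by 0.41 ± 0.09 (adjusted p = 0.0035) and CDK9 by 0.33 ± 0.08 (adjusted p = 0.00842). AFF1 (-0.96 ± 0.25) and KMT2A (-0.68 ± 0.18) were lost without DMSO 1 (adjusted p = 0.0501 and 0.0523), and KMT2A shares 20.2% of its words with other genes. Without DMSO 1 only 2 of the 26 fell, 4 fell without DMSO 2, Combo 3 or Combo 4, and 0 or 1 rose whichever library other than DMSO 1 was left out.

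Myeloid genes moved in both directions with Combo. MPO rose to 5237 ± 536 (log2 fold change 2.61 ± 0.23, limma adjusted p = 1.34e-06), LYZ to 15960 ± 4610 (2.65 ± 0.22, adjusted p = 7.9e-07) and KIT (ENSG00000157404, chr4:54657918-54740715), the stem cell factor receptor gene, from 33.61 ± 23 to 118.5 ± 22.8 (2.00 ± 0.39, adjusted p = 0.00158). ITGAM (ENSG00000169896, chr16:31259967-31332892), which encodes CD11b of mature myeloid cells, fell from 990.6 ± 228 to 218.8 ± 46.8 (-2.17 ± 0.34, adjusted p = 0.000333). The apparent fall of NCF1, an oxidase subunit gene (-3.58 ± 0.36), is uncertain because 49.5% of its words are shared with other genes, among them its pseudogene NCF1B. Of 49 monocyte and macrophage markers 13 rose and 9 fell, and the list as a whole was not called (camera adjusted p = 0.221). Granulocyte markers were not called either (adjusted p = 0.583; 3 of 22 rose and 2 fell, median -0.02 with a test direction up). CDKN1A fell by 0.60 ± 0.09 (adjusted p = 8.12e-05) and EZH1 rose by 0.50 ± 0.13 (adjusted p = 0.0114), while the list of 8 CDK inhibitors was not called (adjusted p = 0.583; median 0.02 with a test direction down).

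The largest rises with Combo began from near silence. SERPINB2 rose to 116.1 ± 13.1 (log2 fold change 6.34 ± 0.71, limma adjusted p = 7.53e-06) and SERPINB10 (ENSG00000242550) to 129.2 ± 21.7 (5.25 ± 0.36, adjusted p = 4.76e-08). LUM (ENSG00000139329, chr12:91102629-91111831) rose from 1.237 ± 1.53 to 69.34 ± 15.5 (5.23 ± 0.47, adjusted p = 5.05e-07). The cytokine-like gene CYTL1 (chr4:5014586-5019472) was not detected in DMSO and averaged 43.91 ± 15.2, at least 54.2-fold higher, and NME8 averaged 29.54 ± 16.2, at least 36.5-fold higher. TFAP2C (chr20:56629302-56639283), a factor of germ cells and trophectoderm, rose from 4.026 ± 2.41 to 92.92 ± 20.1 (4.36 ± 0.39, adjusted p = 5.35e-07), and the neuronal factor gene BHLHE22 by 4.57 ± 0.62 (adjusted p = 3.85e-05). The developmental regulators as a list were not called (10 of 51 rose and 8 fell; camera adjusted p = 0.327). Among the largest falls, the cytokine receptor gene CRLF2 (chrX:1187549-1212750) fell from 33.68 ± 10.1 to 1.159 ± 0.563 (-3.98 ± 0.43, adjusted p = 4.05e-06), and PDCD1, the PD-1 gene, from 14.96 ± 5.78 to 0.9285 ± 1.29 (-3.20 ± 0.50, adjusted p = 0.000177). The aldehyde dehydrogenase gene ALDH1A3 fell from 1950 ± 88.8 to 234.3 ± 39 (-3.06 ± 0.18, adjusted p = 1.12e-08), with 26.1% of its words shared with other genes.

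Some ribosomal protein mRNAs and most mitochondrially encoded mRNAs rose with Combo. Of 80 cytosolic ribosomal protein genes 35 rose and none fell, and 58 rose when adjusted over the list alone (median 0.29; camera adjusted p = 4.44e-15, or 0.442 with an estimated correlation). RPS4X, a small-subunit protein gene, rose from 25480 ± 915 to 33460 ± 4080 (log2 fold change 0.39 ± 0.09, limma adjusted p = 0.00516). Shared 31-base words were 14.1% for RPS4X and ran from 3.1% (RPL28) to 46.6% (RPS2) among the ribosomal protein genes examined. After a correction for transcript length and GC content 23 rose. With the replicate number as a block, which is not taken as pairing for Combo, 72 of the 80 rose, or 73 after that correction. The number of risers depended on the libraries used, with 71 without Combo 2, 11 without Combo 1, 15 without Combo 4, 16 without DMSO 2 or DMSO 4, 18 without DMSO 3, 21 without DMSO 1 and 22 without Combo 3. Of 13 mitochondrially encoded mRNAs 11 rose (median 0.62; adjusted p = 1.58e-07, or 0.404), including MT-CYB (0.73 ± 0.17, adjusted p = 0.00644) and MT-ND5 (0.45 ± 0.11, adjusted p = 0.00559). Other genes, mainly nuclear copies, share 5.0% of the words of MT-CYB and 15.1% of those of MT-ND5. Among the mitochondrially encoded mRNAs examined the share ran from 3.5% (MT-ND3) to 63.7% (MT-ATP6). It was above 20% for MT-ATP6, MT-ND2, MT-CO3, MT-ATP8, MT-ND6 and MT-ND4, so these levels are uncertain. With the replicate number as a block 13 of the 13 rose. In oxidative phosphorylation 8 of 46 genes rose (median 0.15; adjusted p = 0.000413, or 0.67). NDUFA4 rose by 0.66 ± 0.12 (adjusted p = 0.000575) and COX7C by 0.41 ± 0.09 (adjusted p = 0.00364). Of these, 3 rose without DMSO 1 or Combo 1, 4 without DMSO 3 and 5 without DMSO 4. In ribosome biogenesis 4 of 55 rose (adjusted p = 0.0441, or 0.679). FBL, a methyltransferase of the nucleolus, rose by 0.39 ± 0.07 (adjusted p = 0.00098) and RRS1 by 0.77 ± 0.14 (adjusted p = 0.000957), and 6 rose without DMSO 2. The remaining 20 of 30 lists were not called, among them interferon-stimulated genes (2 of 44 rose and 10 fell; adjusted p = 0.0528), which were called lower with library size alone as scaling (adjusted p = 0.0471). Their adjusted p with an estimated correlation, tested without that scaling, was 0.404. Leaving out each library in turn gave 2642 to 3583 genes for Combo against DMSO. The 1613 genes higher and 1966 lower became 1824 and 1703 with quantile normalization, and 637 and 426 at a change of at least 2-fold.

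**Figure D4:**
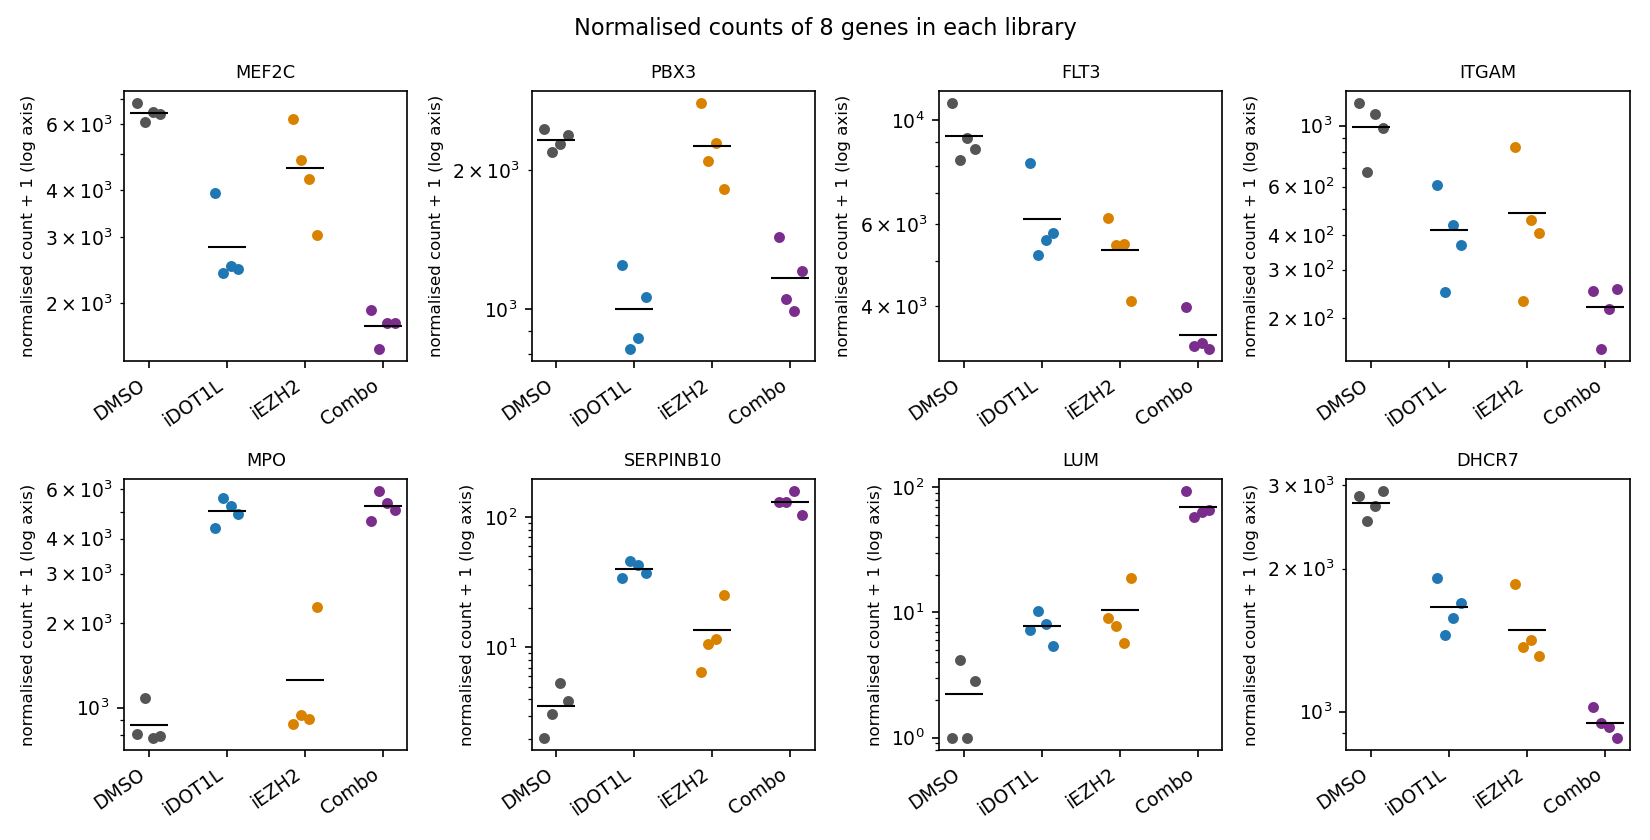
Normalised counts plus 1 on a log axis for MEF2C, PBX3, FLT3, ITGAM, MPO, SERPINB10, LUM and DHCR7, with points for libraries and lines for the means of 4 libraries per group. MPO averages 862.4 in DMSO, 5031 with iDOT1L, 1254 with iEZH2 and 5237 with Combo.

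Combo against iDOT1L showed what GSK126 added to EPZ5676, with 577 genes called, 247 higher and 330 lower. The balance of directions turned with quantile normalization (291 higher and 252 lower), in limma without a trend (169 and 101), at a change of at least 2-fold (95 and 39) and without iDOT1L 1 (122 and 77), iDOT1L 3 (145 and 143), Combo 3 (137 and 118) or Combo 4 (148 and 124). FLT3 fell from 6139 ± 1340 to 3464 ± 352 normalised counts (n = 4; log2 fold change -0.81 ± 0.14, limma adjusted p = 0.00425). LUM rose from 6.726 ± 1.98 to 69.34 ± 15.5 (3.20 ± 0.47, adjusted p = 0.00125), and its neighbour DCN, another proteoglycan gene, by 2.16 ± 0.32 (adjusted p = 0.00162). The lactosylceramide synthase gene B4GALT6 (chr18:31622247-31685836) rose from 13.39 ± 2.92 to 144.2 ± 62 (3.23 ± 0.32, adjusted p = 8.83e-05). Among the 51 developmental regulators 4 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone (median 0.43; camera adjusted p = 0.000122, and 0.00845 with an estimated correlation). HOXB9 rose by 1.87 ± 0.28 (adjusted p = 0.00143) and POU4F1 by 0.69 ± 0.10 (adjusted p = 0.00174). In cholesterol synthesis 12 of 23 fell (median -0.55; adjusted p = 1.25e-18, or 0.325). MVK, mevalonate kinase, fell by 0.74 ± 0.14 (adjusted p = 0.0095). Of 49 monocyte and macrophage markers 9 fell and 1 rose (adjusted p = 0.0045, or 0.587), among them IRF8 (-0.45 ± 0.08, adjusted p = 0.00777). In glycolysis 5 of 23 fell (adjusted p = 8.83e-09, or 0.414), including HK2 (-0.68 ± 0.13, adjusted p = 0.0105), and of 16 epithelial and fibroblast markers 2 rose (adjusted p = 0.0102, or 0.414). MEF2C (-0.67 ± 0.17, adjusted p = 0.0467) was lost without any 1 library except iDOT1L 2 (highest adjusted p = 0.154).

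The other list calls of Combo against iDOT1L rested on few members. Lists shifted up were cytosolic ribosomal proteins (camera adjusted p = 2.38e-11, or 0.587 with an estimated correlation; 0 of 80 called), mitochondrial ribosomal proteins (1.86e-09, or 0.587; 0 of 76), MYC-responsive genes (2.38e-08, or 0.587; 2 of 58 called, both fallen) and ribosome biogenesis (5.32e-08, or 0.587; 1 of 55 rose). The same held for mitochondrially encoded mRNAs (5.81e-07, or 0.538; 0 of 13, and 9 rose over the list alone), oxidative phosphorylation (2.33e-06, or 0.587; 0 of 46), S phase (0.0163, or 0.795; 0 of 44), G2 and M phase (0.0394, or 0.77; 0 of 54) and translation factors (0.0442, or 0.587; 0 of 50). Lists shifted down were the DOT1L, super elongation and KMT2A complexes (0.0202, or 0.538; 0 of 26) and immediate early genes (0.0413, or 0.587; 1 of 23 fell). The remaining 14 of 30 lists were not called, among them the KMT2A-fusion and HOXA list (2 of 30 rose and 4 fell; adjusted p = 0.13). Leaving out each library in turn gave 199 to 567 genes, with 199 without iDOT1L 1, 288 without iDOT1L 3, 377 without iDOT1L 4, 374 without Combo 1, 255 without Combo 3 and 272 without Combo 4.

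Combo against iEZH2 showed what EPZ5676 added to GSK126, with 850 genes called, 465 higher and 385 lower. MEF2C fell from 4578 ± 1290 to 1745 ± 171 normalised counts (n = 4; log2 fold change -1.35 ± 0.17, limma adjusted p = 0.000166), MEIS1 from 1481 ± 302 to 722.0 ± 58.3 (-1.01 ± 0.13, adjusted p = 0.000159) and PBX3 from 2249 ± 410 to 1171 ± 198 (-0.94 ± 0.14, adjusted p = 0.000534). MPO rose from 1254 ± 690 to 5237 ± 536 (2.19 ± 0.23, adjusted p = 4.66e-05) and LYZ by 1.91 ± 0.22 (adjusted p = 0.000104). CDKN1A fell by 0.39 ± 0.09 (adjusted p = 0.0147) but was lost without iEZH2 1, iEZH2 3 or Combo 3 (highest adjusted p = 0.0583). Of the 30 genes of the KMT2A-fusion and HOXA list 15 fell and none rose (median -0.50; camera adjusted p = 8.02e-15, or 0.178 with an estimated correlation), including HMGA2 (-1.38 ± 0.16, adjusted p = 5.57e-05) and the SUMO protease gene SENP6 (-0.81 ± 0.12, adjusted p = 0.000434). Of 49 monocyte and macrophage markers 12 rose and 2 fell (median 0.33; adjusted p = 6.3e-07, or 0.249), including MNDA (2.23 ± 0.21, adjusted p = 1.36e-05), CCR2 (2.02 ± 0.25, adjusted p = 0.000134) and the bacterial lipoprotein receptor gene TLR2 (0.93 ± 0.13, adjusted p = 0.000328). In MHC class II 3 of 10 rose (adjusted p = 0.0023, or 0.227). HLA-DQB1 rose by 1.71 ± 0.29 (adjusted p = 0.00132) and CD74 by 0.66 ± 0.13 (adjusted p = 0.00455). CYTL1 rose from 0.8106 ± 1.1 to 43.91 ± 15.2 (4.77 ± 0.45, adjusted p = 9.77e-06), and IMPG1, a retinal proteoglycan gene, fell from 36.67 ± 5.93 to 4.949 ± 2.21 (-2.75 ± 0.48, adjusted p = 0.00194). FLT3 fell by 0.60 ± 0.14 (adjusted p = 0.0165) but was lost without iEZH2 1 or 3 or Combo 3 or 4 (highest adjusted p = 0.0695).

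The other list calls of Combo against iEZH2 held few single genes. Lists shifted up were cytosolic ribosomal proteins (camera adjusted p = 3.6e-13, or 0.503 with an estimated correlation; 0 of 80 called), mitochondrially encoded mRNAs (0.000377, or 0.503; 0 of 13), granulocyte markers (0.0223, or 0.227; 2 of 22 rose, among them BPI by 0.92 ± 0.20) and MHC class I (0.0446, or 0.249; 1 of 15 rose). Lists shifted down were cholesterol synthesis (7.62e-07, or 0.424; 2 of 23 fell, among them DHCR7 by 0.64 ± 0.11), glycolysis (7.62e-07, or 0.265; 4 of 23 fell) and S phase (2.85e-06, or 0.508; 0 of 44). Lower too were ATF4 and the unfolded protein response (0.00195, or 0.503; 1 of 30 rose and 3 fell, among them XBP1 by 0.70 ± 0.14), G2 and M phase (0.00218, or 0.524; 1 of 54 fell), aminoacyl-tRNA synthetases (0.0126, or 0.524; 0 of 20) and MYC-responsive genes (0.0441, or 0.726; 1 of 58 fell). The remaining 16 of 30 lists were not called, among them the developmental regulators (1 of 51 rose and 3 fell; adjusted p = 0.438). Leaving out each library in turn gave 493 to 1349 genes, with 550 without iEZH2 1, 493 without iEZH2 3, 1349 without iEZH2 4 and 532 without Combo 3.

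The single treatments differed from each other in 1550 genes, 866 higher and 684 lower with iDOT1L. PBX3 was lower with iDOT1L (999.1 ± 195 against 2249 ± 410 normalised counts, n = 4; log2 fold change -1.17 ± 0.14, limma adjusted p = 3.86e-05), as was MEIS1 (-0.75 ± 0.13, adjusted p = 0.00137), while MPO (2.13 ± 0.23, adjusted p = 3.21e-05) and LYZ (1.11 ± 0.22, adjusted p = 0.00445) were higher. MEF2C (-0.68 ± 0.17, adjusted p = 0.0216) and CDKN1A (-0.33 ± 0.09, adjusted p = 0.0242) were lower. MEF2C was lost without iDOT1L 2, 3 or 4 or iEZH2 1, 2 or 3 (highest adjusted p = 0.0703), and CDKN1A without iDOT1L 2 or 3 or iEZH2 1 or 3 (highest adjusted p = 0.0831). Of the 30 genes of the KMT2A-fusion and HOXA list 14 were lower and 2 higher (median -0.42; camera adjusted p = 3.1e-09, or 0.169 with an estimated correlation). Of 49 monocyte and macrophage markers 20 were higher and none lower (median 0.48; adjusted p = 2.47e-12, or 0.169), including the fractalkine receptor gene CX3CR1 (1.49 ± 0.17, adjusted p = 2.81e-05) and CCR2 (2.14 ± 0.25, adjusted p = 3.86e-05). Of 51 developmental regulators 10 were lower and 1 higher with iDOT1L (median -0.22; adjusted p = 0.000104, and 0.00785 with an estimated correlation). DLX5 (chr7:97020392-97024950), a factor of bone and forebrain, averaged 242.4 ± 27.5 against 882.5 ± 204 (-1.83 ± 0.15, adjusted p = 1.38e-06), FOXD1, a kidney stroma factor, 485.0 ± 73.5 against 1353 ± 219 (-1.47 ± 0.16, adjusted p = 1.88e-05), and HOXB9 (chr17:48621159-48626356) 11.76 ± 3.32 against 89.54 ± 20.2 (-2.84 ± 0.28, adjusted p = 6.24e-06). B4GALT6 was lower (-2.90 ± 0.32, adjusted p = 2.02e-05), as was the adenosine receptor gene ADORA1 (-3.02 ± 0.41, adjusted p = 0.000118), and MEGF6 was higher (3.03 ± 0.42, adjusted p = 0.000326). HOXA9 was lower (-0.38 ± 0.09, adjusted p = 0.0134) but was lost without iEZH2 3 (adjusted p = 0.0531).

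Growth-related lists were shifted lower with iDOT1L than with iEZH2, with a minority of members called. These were MYC-responsive genes (8 of 58 lower and 1 higher; camera adjusted p = 6.71e-12, or 0.353 with an estimated correlation), S phase (4 of 44 lower, and 20 over the list alone; 6.77e-11, or 0.353), and mitochondrial ribosomal proteins (5 of 76 lower, including MRPS6 at -0.94 ± 0.10; 9.57e-11, or 0.376). So were ribosome biogenesis (3 of 55 lower; 2.74e-08, or 0.387) and G2 and M phase (3 of 54 lower, including CCNB1 at -0.44 ± 0.09; 9.52e-07, or 0.353). Lower too were aminoacyl-tRNA synthetases (0 of 20; 0.0022, or 0.414), ATF4 and the unfolded protein response (2 of 30 called, both higher; 0.0115, or 0.44) and oxidative phosphorylation (1 of 46 lower; 0.0128, or 0.685). Interferon-stimulated genes were lower as a list (6 of 44 lower and 4 higher; 0.0219, or 0.232), with the antiviral synthetase gene OAS3 at -2.62 ± 0.30, and so were p53 targets (3 of 24 lower; 0.0482, or 0.169). Higher with iDOT1L were cholesterol synthesis (2 of 23 higher; 3.05e-05, or 0.387), MHC class II (3 of 10 higher, including CD74 at 0.96 ± 0.13; 0.0022, or 0.169), erythroid and megakaryocyte markers (2 of 15 higher, including CA2 at 0.82 ± 0.14; 0.0482, or 0.169) and granulocyte markers (4 of 22 higher and 3 lower, including BPI at 1.45 ± 0.20; 0.0491, or 0.169). The remaining 13 of 30 lists were not called. With replicates as pairs 3185 genes were called. Lower with iDOT1L were then 32 genes of the MYC list, 22 of ribosome biogenesis, 21 of S phase, 19 of mitochondrial ribosomal proteins, 14 of G2 and M phase, 11 of ATF4 and the unfolded protein response, 8 aminoacyl-tRNA synthetases, 5 p53 targets, 3 of oxidative phosphorylation and 1 monocyte and macrophage marker. Higher were 14 of cholesterol synthesis, 5 of MHC class II, 4 of the KMT2A-fusion list, 2 developmental regulators and 2 p53 targets. CDK6 (adjusted p = 0.00383) and HOXA10 (adjusted p = 0.0114) were called lower. As lists, granulocyte markers (adjusted p = 0.0571) and erythroid and megakaryocyte markers (adjusted p = 0.0569) were no longer called, and granulocyte markers were also lost with library size alone as scaling (adjusted p = 0.0511). Leaving out each library in turn gave 964 to 1802 genes, with 964 without iEZH2 3.

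No gene was called as departing from the sum of the single effects in Combo. The interaction of the compounds gave 0 genes past a BH-adjusted p of 0.05 in limma (lowest adjusted p = 0.0895), 1 gene in limma without a trend and 0 with replicates as pairs. At an unadjusted limma p under 0.05 there were 848 genes (3.8% of those tested), a smaller share than the 0.05 that chance alone would give. Without DMSO 3, DMSO 4 or iEZH2 4 the interaction gave 1 gene. MEF2C, FLT3, MPO and LYZ each had an adjusted interaction p of 1. The median SE of the interaction was 0.32, or 0.176 among 12270 genes with a mean of at least 50 normalised counts, and the 95% interval lay within 1 log2 unit for 11364 of these. In libraries with planted changes the interaction test found 35.2% of 2-fold and 54.3% of 4-fold changes, or 67.3% and 93.1% at a mean of at least 50, so smaller departures would be missed. As lists, immediate early genes lay above the sum of the single effects (median 0.22; camera adjusted p = 4.39e-05, or 0.5 with an estimated correlation; 3 of 23 over the list alone). Above it too were cytosolic ribosomal proteins (0.08; adjusted p = 0.00495, or 0.94) and mitochondrial ribosomal proteins (0.07; adjusted p = 0.0116, or 0.94, and 0.0516 with library size alone as scaling). G2 and M phase (-0.08; adjusted p = 0.00116, or 0.94) and S phase (-0.12; adjusted p = 0.0024, or 0.94) lay below it. The remaining 25 of 30 lists were not called, with cholesterol synthesis at adjusted p = 0.135.

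Genes called with a single compound were mostly called in the same direction with Combo. Of the 1396 genes of iDOT1L, 1083 moved the same way in Combo (510 up and 573 down, 77.6%), including MEF2C, PBX3, MPO and CCR2, and 3 moved the opposite way. Of the 748 genes of iEZH2, 630 moved the same way (248 up and 382 down, 84.2%), including DHCR7, FLT3 and INSIG1, and 1 moved the opposite way. Between the single treatments 244 genes moved the same way (88 up and 156 down, 17.5% of the iDOT1L genes), including FLT3 and DHCR7, and 23 the opposite way. Independent lists would share 112, 61.3 and 23.5 genes. These comparisons share the DMSO libraries. Simulated unchanged groups set against a common simulated DMSO group shared at most 0, 1 and 0 genes, which says little because such groups give hardly any calls. With the DMSO libraries split between the comparisons the shared numbers were 424 to 533, 130 to 301 and 46 to 86. The correlation of the effects was 0.67, 0.626 and 0.488 against 0.501, 0.5 and 0.5 in the simulations, and with the DMSO libraries divided between the comparisons it was 0.3 to 0.363, 0.227 to 0.295 and 0.076 to 0.152. The covariance of the effects was 0.2214, 0.1897 and 0.1215 against 0.0812, 0.081 and 0.0809 in the simulations.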

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

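The checks for a library standing apart and for a list departing from the sum of the single effects were fixed before the data were examined, while the length and GC, scaling and single-library tests of the cholesterol and ribosomal patterns were chosen only after those results were seen.

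In 40 of 544 sets of 4 libraries (the gene lists, 104 genes, depth and the share of the most abundant gene, each in 4 groups) the highest or lowest library lay far from the other 3 of its group by Dixon's test at the 95% level. Chance gives about 1 in 20 such sets, or 27.2, and the sets are not independent. DMSO 2 stood apart in 8, iEZH2 4 in 6, Combo 1 in 5 and iDOT1L 1 in 4 of them, every other library in 3 or fewer, and none in depth or that share. Among list scores, relative to the DMSO mean, these were the KMT2A-fusion and HOXA programme in iDOT1L 1 (-0.3358), cytosolic ribosomal proteins in DMSO 2 (-0.0866), mitochondrial ribosomal proteins in iDOT1L 1 (-0.271), PRC2 subunits in DMSO 2 (0.0378) and Combo 3 (-0.0144), cholesterol synthesis in DMSO 2 (-0.2178) and epithelial and fibroblast markers in iDOT1L 2 (-0.0167).

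Single genes with a library far from the other 3 are given in normalised counts. In DMSO 2 they were DOT1L (6946), MPO (1078), CD74 (3113), BPI (230) and CX3CR1 (676.9), in DMSO 1 EZH2 (1578) and CDK9 (1281), in DMSO 3 SERPINB2 (3.242) and in DMSO 4 SMN2 (12.56). In iDOT1L 1 they were MEF2C (3933) and CCNB1 (2002), in iDOT1L 3 CD34 (27.07), and in iDOT1L 4 TLR4 (224.2) and CYTL1 (12.29). In iEZH2 1 they were EZH2 (1842) and NDUFA4 (1872), in iEZH2 2 CDK9 (1130), and in iEZH2 4 MPO (2288), LYZ (6541), NR4A1 (54.28), SENP6 (3934), CDKN2A (1.712) and CA2 (424.6). In Combo 1 they were DOT1L (4235), CD34 (1.539), FLT3 (3988), HLA-DQB1 (122.2) and LDHA (21533), in Combo 2 CDK6 (7361) and CYTL1 (66.73), in Combo 3 CDKN2B (1.923) and RTL9 (0.8081), and in Combo 4 BHLHE22 (25.41). No cause was tested for single libraries.

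In 5 lists the effect of Combo differed from the sum of the single effects in the camera test of the interaction, with medians of 0.082 for cytosolic and 0.0706 for mitochondrial ribosomal proteins, -0.1197 for S phase, -0.0759 for G2 and M phase and 0.224 for immediate early genes. With a correlation estimated per list none of the 5 passed (adjusted p = 0.94 for the first 4 and 0.5 for immediate early genes), so these departures rest on the preset correlation.

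The cholesterol synthesis list was lower with iEZH2 than in DMSO by a mean of -0.658 (SE 0.1351). After each library's trend on transcript length and GC content was removed the difference was -0.647, the list's median lay -0.6389 from that of all genes, and leaving out single libraries gave -0.5725 at the smallest (without iEZH2 2), more than 2 SE below 0 in 8 of 8 fits. These values argue against length and GC content, scaling between libraries or a single library as the whole cause. Culture conditions that moved with the treatment, such as cell density, stay open. An effect of GSK126 on sterol sensing may underlie the fall and was not tested.

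The cytosolic ribosomal protein list was higher in Combo than in DMSO by a mean of 0.2825 (SE 0.1215). The difference was 0.2365 after the length and GC correction (SE 0.0966), which argues against that trend as the whole cause, although 23 rather than 35 members rose and fold changes fell with length over all genes (rank correlation -0.184). The list's median lay 0.3171 above that of all genes, within 2 SE of the 0.1 that was set as a bound for scaling. The test thus did not decide by its bound, but that SE measures the spread between libraries. A factor that moves all genes of a library alike would not part the list from them. The median of all genes at a mean of at least 50 was -0.0272, -0.0072 with library size alone and 0.0208 with quantile normalization. These values argue against such a common factor as the whole cause. A single library stays open as a cause, since without Combo 1 the difference was 0.1836 (SE 0.0955). The difference exceeded 2 SE in 5 of 8 fits without 1 library, and 11 to 71 members rose. A biological rise was not tested.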

How the results depend on the processing

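Library quality weights, deposited values without back-transformation, matched IDs alone, the groups compared with a replicate block, and the tests on other splits of the libraries were chosen only after the results were seen.

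The counts of calls depended on how the spread was modelled, while scaling, filters, pseudocounts, matched IDs and deposited values kept each within 1.5 times. No called change of a named gene reversed its direction. No list call did so either, but all lists were retested only with an estimated correlation, with the block and with library size alone. The balance of higher and lower calls did turn. With quantile normalization it went from 687 and 709 to 722 and 680 for iDOT1L, from 1613 and 1966 to 1824 and 1703 for Combo against DMSO and from 247 and 330 to 291 and 252 for Combo against iDOT1L, and with the block from 465 and 385 to 966 and 1170 for Combo against iEZH2. With library size alone it was 731 and 636 for iDOT1L, with matched IDs alone 660 and 654, and without a trend 533 and 490 for iDOT1L and 169 and 101 for Combo against iDOT1L. For iDOT1L it also turned without DMSO 1 (588 and 509), DMSO 3 (535 and 501), DMSO 4 (518 and 476), iDOT1L 2 (554 and 542), iDOT1L 3 (466 and 449) or iDOT1L 4 (546 and 507). A change of at least 2-fold gave more genes higher than lower in all 6 comparisons. Across all alternatives, calls of named genes were lost 522 times and gained 434 times. List calls were lost 88 times with an estimated correlation, 4 times with the block (10 gained) and 3 times with library size alone (1 gained). Fits by edgeR, DESeq2 or voom and RLE size factors need counts and were not run. Estimated depth was 20.7 to 27.3 M reads, and planted 2-fold changes were found in 46.9% for iDOT1L overall but 87.5% at a mean of at least 50, so changes in weakly expressed genes can be missed.

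Values follow for iDOT1L, iEZH2 and Combo against DMSO, Combo against iDOT1L, Combo against iEZH2, and iDOT1L against iEZH2, in this order unless named. A change of at least 2-fold, stricter by construction, left 466, 176, 1063, 134, 303 and 421 genes. With the replicate number as a block the counts were 2729, 2180, 5499, 2240, 2136 and 3185. The comparisons of Combo are not taken as paired, since replicates of a number correlated at 0.033 to 0.361, 0.088 to 0.4 and 0.09 to 0.436, not all above 0.1. Replicates of a number were each other's best partner in 1, 2 and 2 of 4 pairs. In the comparisons taken as paired this held for 3 (iDOT1L and DMSO), 2 (iEZH2 and DMSO) and 2 (iDOT1L and iEZH2), so it does not separate them. The division rests on the limit of 0.1 alone, although the numbers run through all 4 groups. Against DMSO the block added calls for aminoacyl-tRNA synthetases (adjusted p = 0.0156) and G2 and M phase (0.0314) with Combo. It also added PRC2 subunits (0.0333), DOT1L complexes (0.0228) and immediate early genes (0.0386) in Combo against iEZH2, and MYC (0.0105), granulocyte (0.0359) and cholesterol (0.00176) lists in the interaction. With an estimated correlation none of these 8 passed (adjusted p = 0.506, 0.657, 0.168, 0.263, 0.325, 0.793, 0.464 and 0.782). Beyond these and those given with each paired comparison it changed no list call. Only the groups compared with the block gave 3611 for iDOT1L, 2052 for iEZH2, 1210 for Combo against iDOT1L and 3612 between single treatments. Library quality weights gave 2301, 1373, 1416, 1462 and 2377, leaving aside Combo against DMSO, which stayed within 1.5 times. Limma without a trend gave 450 for iEZH2, 270 for Combo against iDOT1L and 1 for the interaction, and only the groups compared gave 450 for iEZH2, 511 for Combo against iEZH2 and 1004 between single treatments. Apart from the 2-fold limit the cause was not tested.

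Single libraries left out gave 915 to 1279 (915 without iDOT1L 3), 409 to 1046 (442 without DMSO 1, 409 without DMSO 3, 439 without DMSO 4, 473 without iEZH2 3), 2642 to 3583, 199 to 567 (199 without iDOT1L 1, 288 without iDOT1L 3, 377 without iDOT1L 4, 374 without Combo 1, 255 without Combo 3, 272 without Combo 4), 493 to 1349 (550 without iEZH2 1, 493 without iEZH2 3, 1349 without iEZH2 4, 532 without Combo 3) and 964 to 1802 (964 without iEZH2 3), and 0 to 1 for the interaction (1 without DMSO 3, DMSO 4 or iEZH2 4). Overlaps of iDOT1L with Combo, iEZH2 with Combo and iDOT1L with iEZH2 were 551, 249 and 88 at adjusted p under 0.01, 2066, 1736 and 778 with the block, 2236, 1511 and 858 with the groups compared and the block, and 1746, 1119 and 503 with quality weights. The latter 2 were 375 and 139 without a trend and 383 and 158 with only the groups compared. Without single DMSO libraries overlaps were 787 to 943, 346 to 679 and 138 to 263, with 375 and 145 for the latter 2 without DMSO 1, 346 and 138 without DMSO 3, and 374 and 144 without DMSO 4.

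Of the 35 splits of the 8 libraries, fitted with only the groups compared, 1, the real one, gave so many genes in each comparison. Real and highest other counts were 1390 and 13, 450 and 46, 3528 and 4, 465 and 14, 511 and 90, and 1004 and 26. For the 3 comparisons of Combo, 1 of 35 is the smallest share that the test can give and takes the replicate numbers as unpaired. If the numbers do pair these libraries, the remaining splits are too few here too. A chance division is thus unlikely if they are unpaired, but not excluded. For the 3 paired comparisons the 8 splits that part all pairs are too few for a share under 0.05 (highest other 0, 0 and 2), and the others mix the pairs. For the interaction the real count was 0, so 100 of 100 regroupings reached it by construction (up to 2603, since they mix the treatment effects) and the test decides nothing.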

Other observations

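The genes in these paragraphs were chosen after their values were seen, and the tests of neighbouring genes were chosen before their results.

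CD38 (ENSG00000004468), an ectoenzyme gene, fell from 281.6 ± 105 normalised counts in DMSO to 81.93 ± 34.5 with iDOT1L (n = 4; log2 fold change -1.78 ± 0.38, limma adjusted p = 0.00889) and 64.15 ± 14.9 with Combo (-2.08 ± 0.38, adjusted p = 0.00116), but did not pass with iEZH2 (0.14). ITGAX (ENSG00000140678), which encodes CD11c, fell from 327.6 ± 115 to 63.7 ± 16.8 with Combo (-2.29 ± 0.29, adjusted p = 2.51e-05). Its falls with iDOT1L (-1.13 ± 0.29, adjusted p = 0.0254) and iEZH2 (-1.21 ± 0.29, adjusted p = 0.0274) were lost without DMSO 1, 3 or 4, the first also without iDOT1L 2 or 3 (highest adjusted p = 0.0925) and the second without iEZH2 2, 3 or 4 (highest adjusted p = 0.105). CYBB (ENSG00000165168), the membrane subunit of the phagocyte oxidase, rose from 72.44 ± 34.2 to 331.3 ± 39.1 with Combo (2.27 ± 0.23, adjusted p = 2.07e-06) and by 1.04 ± 0.23 with iDOT1L (adjusted p = 0.00937). With iEZH2 CYBB did not pass (0.72), although it was called without DMSO 3 or iEZH2 1 (lowest adjusted p = 0.00845) and with replicates as pairs (adjusted p = 0.0497). CD38 and CYBB with iDOT1L, and CD38, ITGAX and CYBB with Combo, were called in 8 of 8 fits without 1 library.

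Some silent or weakly expressed genes rose together with a neighbour. OLIG2 (chr21:33025845-33029196), a factor of the oligodendrocyte lineage, rose from 10.51 ± 4.77 to 48.79 ± 8.26 with iDOT1L (log2 fold change 2.21 ± 0.36, limma adjusted p = 0.000597) and its neighbour OLIG1 (chr21:33070144-33072420) from 372.5 ± 67.5 to 1103 ± 207 (1.56 ± 0.24, adjusted p = 0.000623). With iEZH2 neither passed (0.85 and 0.64), though OLIG1 did with replicates as pairs (adjusted p = 0.0147), and with Combo both rose (1.91 ± 0.36 and 1.83 ± 0.24). SLAIN1 (chr13:77697854-77764242), a microtubule gene, rose from 6.404 ± 3.65 to 22.11 ± 2.63 with iDOT1L (1.82 ± 0.37, adjusted p = 0.00424), 30.14 ± 10.1 with iEZH2 (2.18 ± 0.37, adjusted p = 0.00223) and 91.2 ± 10.2 with Combo (3.82 ± 0.37, adjusted p = 1.09e-06). The next protein-coding gene tested, POU4F1, rose by 0.51 ± 0.10, 0.80 ± 0.10 and 1.20 ± 0.10, with 27.2% of its 31-base words shared. LUM and DCN (chr12:91140484-91183123) lie side by side, and with Combo DCN rose from 6.758 ± 1.56 to 45.41 ± 9.99 (2.57 ± 0.32, adjusted p = 1.8e-05) beside the rise of LUM. Each of these calls held in 8 of 8 fits without 1 library.

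One hypothesis is that domains of neighbouring genes respond together when H3K79 or H3K27 methylation is inhibited. Among 16768 protein-coding genes tested, neighbouring pairs over 5 kb apart with both genes raised numbered 7 with iEZH2, 39 with iDOT1L and 149 with Combo. In 100 shuffles of the calls among genes of similar level the highest numbers were 6, 24 and 93 (medians 2, 12.5 and 69). Pairs sharing no 31-base word numbered 7, 36 and 142, so shared reads do not account for most of them. Pairs of lowered genes were also more frequent than in any shuffle (15, 50 and 188 against at most 12, 25 and 133), so the pattern is not particular to genes released from silencing. The counts suggest that position may matter, as a domain response predicts, but clustering of genes with related function was not separated from it, chromatin marks were not measured here, and with iEZH2 the margin was 1 pair.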
